A study of Mus musculus with 2 samples.

How the data were processed

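The samples were 2 DNase-seq libraries of gastrocnemius from female B6CASTF1/J mice aged 10 days, labelled biological replicates 1 and 2 of a single group, made by an ENCODE production laboratory. For each library the authors deposited 2 peak lists, a list of short intervals with a false discovery rate (FDR), and a list of footprints, all on mm10. Per the labels the filtered alignments of each library alone went into its peaks, and the libraries were not pooled before calling. The aligner, the peak caller, the footprint caller, their versions and thresholds are not given in the sources used here. The value of each deposited peak is a signal, a height normalized to read depth by the authors. Heights were whole multiples (within 0.05 of a step, for heights under 100 steps) of 0.00597 in replicate 1 and 0.0107 in replicate 2; if heights are per 1 M reads these steps stand for 168 M and 93.3 M reads, a scale inferred from the values only. The deposited interval files give an FDR, a p-value corrected by the authors, of at most 0.05. The deposited footprint lists hold 0.01 in their score column for every footprint, so footprints could not be ranked.

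In the shorter peak list of each library every peak held a base with an FDR under 0.001 and in the longer list under 0.05. The rule set beforehand took the list with narrower peaks or, at equal width, the stricter. Median widths were 180 bp in both lists of replicate 1, and 220 bp in the shorter and 215 bp in the longer list of replicate 2; these were treated as equal and the stricter list was used, with the other as an alternative.

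Gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named 36 genes of muscle and other cell types whatever their values, up to 4 members per list with a promoter peak in both libraries that had the most shared distal peaks, up to 4 members without one in either, the 10 genes with the most shared distal peaks and the 10 shared peaks with the best sum of height ranks. Genes named after their values were seen are said to be so. The 29 lists covered 9 muscle lists, 9 lists of other cells found in or around muscle (fibro-adipogenic, tenocyte, endothelial, mural, Schwann, macrophage, lymphocyte, erythroid, adipocyte), other tissues (cardiac, hepatocyte, neuron, germline, pancreas, keratinocyte), housekeeping, circadian and immediate-early genes, and hindlimb and forelimb position genes. Of 451 list entries, 4 were not found among the 21911 protein-coding genes of GENCODE M21. After the neuron list was seen to stand out, 7 neural lists were added.

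A peak was shared when a peak of the other library overlapped at least 50% of either of the pair, and shared peaks are those of replicate 1. Peaks were counted as deposited, although some overlap others of the same list, and merged peaks were an alternative added after seeing the data. Shuffled positions came from 100 draws within chromosomes. A promoter peak lay within 1 kb of any annotated TSS of a protein-coding gene, and a distal peak lay farther from every TSS and within 50 kb of a TSS of its gene. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests on promoter peaks, and by their mean number of distal peaks against 10000 random lists of the same size and promoter status, two-sided, each with Benjamini-Hochberg adjustment over the 29 lists; adjusted values are over the list family alone, as no test ran over all genes. Libraries were compared at the 26804 tallest peaks of each, with two-sided exact McNemar tests of promoter peaks and, chosen after seeing the data, random lists for the difference in distal peaks. These p-values describe these libraries, since genes and peaks are not replicates. The smallest p that 10000 random lists can give is 0.0002, which over 29 lists is an adjusted 0.0029 when 2 lists reach it.

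Motifs were 22 consensus sequences, matched on either strand in the central 150 bp of peaks and in windows 1 kb to each side, with the GRCm38 sequence, Fisher's exact test and Wald 95% intervals (0.5 added to each cell where a cell was 0), adjusted over 22 motifs. Footprint motifs were matches per base inside footprints with 5 bp on each side against the rest of the peaks, with exact conditional intervals for the ratio of rates. Counts of the 2 libraries were added, and each library was also taken alone. The intervals take all matches as independent, although a match in peaks of both libraries enters the added counts from each. Shares carry Wilson intervals for counting error only. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with bedtools 2.31.1 as a check.

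The code was tested on simulated data. Overlaps differed from bedtools in 0 of 2563 pairs; of 200 random lists, 3 had an unadjusted p under 0.05 in the promoter test and 5 in the distal test. Of planted lists of 15 genes, 0 of 50 were missed in the promoter test and 6 of 20 lists with 1.5 added distal peaks per gene were missed in the distal test, so a difference of that size may go uncalled. These list tests ran on shared peaks. The exact interval for a rate ratio missed the true ratio in 31 of 500 simulations.

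Alternatives were a stricter selection of each list, the other deposited list, equal numbers of tallest peaks, overlaps of 1 bp and of at least 50% of both peaks, each library alone, promoter distances of 500 bp and 2 kb, distal windows of 25 and 100 kb, CpG classes, random lists matched on gene density or unmatched, shuffled sequences, a central 75 bp and unpadded footprints. Alignments and coverage tracks were not used here. Sequence variants between the parental strains were not analysed here. Values of some single genes are not reported here.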

Results

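DNase-seq, which reads out open chromatin as sites that the enzyme DNase I cuts, was measured in the gastrocnemius, a hindlimb calf muscle, of female B6CASTF1/J mice aged 10 days. There was 1 group with 2 libraries, labelled biological replicates 1 and 2, each from pooled animals, and no other condition. The stricter peak list held 114758 peaks in the library labelled replicate 1 and 26804 in the library labelled replicate 2, covering 21.6 and 6.72 Mb of the mm10 genome, with a median width of 180 and 220 bp. Median depth-normalized peak height was 1.18 and 1.48. Read totals are not used here; the spacing of the height values puts the depth of replicate 1 at 1.80 times that of replicate 2, if the heights share a scale. Values per library carry no replicate error, since each library was called alone, and differences between the libraries are themselves the replicate spread.

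The first question was how far the 2 libraries mark the same sites. Over the whole lists the overlap of peaks depended on place in replicate 1 far more than in replicate 2: 41.4% of the promoter peaks of replicate 1 (within 1 kb of a transcription start site, TSS) but 7.96% of its distal peaks overlapped a peak of replicate 2, against 70.3% and 70.5% in the other direction. In all, 19119 peaks of replicate 1 (16.7%) and 18853 of replicate 2 (70.3%) were shared, where shuffled positions on the same chromosomes gave means of 0.330% and 1.37%. With each list limited to its 26804 tallest peaks, 45.8% were shared in both directions, with 65.4% of promoter and 27.2% of distal peaks of replicate 1 and 49.4% and 39.2% of those of replicate 2. Among the tallest 10% of peaks the shared part was 61.8% in replicate 1 and 89.0% in replicate 2, and in the lowest 10% it was 2.54% and 29.5%. Across the 20104 shared pairs, which are not independent replicates, heights had a Spearman correlation of 0.62 and a Pearson correlation on the log scale of 0.61.

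Shared peaks sat mostly at promoters: 64.7% (Wilson 95% interval 64.0 to 65.3) lay within 1 kb of a TSS, where shuffled positions gave 4.38%, and 2.42% lay in exons, 11.4% in introns and 21.5% between genes. The 2 libraries differed here. Promoters took 26.0% of all peaks of replicate 1, 48.6% of its 26804 tallest peaks and 64.6% of the peaks of replicate 2.

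**Figure D1:**
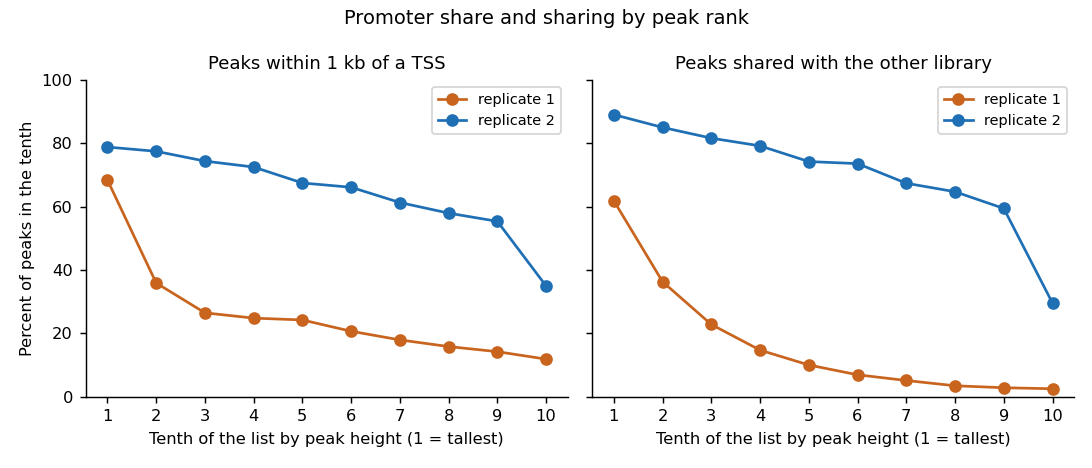
Percent of peaks within 1 kb of a TSS (left) and percent shared with the other library (right) for each 10% step of the peak list, ordered from the tallest to the lowest peaks (x axis), with a line per library. Promoter share falls from 68.4% to 11.9% in replicate 1 and from 78.8% to 34.9% in replicate 2.

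The second question was which genes of muscle and of the other cell types in the tissue carried a promoter peak shared by the 2 libraries. Housekeeping and clock genes did so most often and macrophage, endothelial and cardiac markers least often, an order that in part follows the CpG content of their promoters. A shared promoter peak was found at 13 of 15 housekeeping genes, among them Actb (cytoplasmic actin) and Polr2a, and at 13 of 15 circadian clock genes, among them Per1, Nr1d1, Cry2 and Bhlhe41, against 45.0% of other protein-coding genes (log2 odds ratio 2.99 and adjusted p = 0.00724 for each list, Fisher's exact test over 29 lists). Muscle identity genes were split. Ckm, the muscle creatine kinase, had a promoter peak at the same position in both libraries (chromosome 7, 19405501 to 19405660), of height 2.63 in replicate 1 and 3.46 in replicate 2. Actn3, the alpha-actinin of fast fibres, also had promoter peaks in both, the highest of 14.7 and 5.02, as did Slc2a4, the insulin-responsive glucose transporter, with 6.28 and 3.15.

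Of the 9 muscle lists, the sarcomere list had fewer shared promoter peaks than other genes (7 of 30, log2 odds ratio -1.43, adjusted p = 0.0351, Fisher's exact test) and the other 8 were not called. Their counts were 12 of 20 for myogenic regulators, 8 of 15 for satellite cell genes, 6 of 15 for muscle metabolism and for the neuromuscular junction, 4 of 15 for slow fibres, 3 of 15 for fast fibres and for excitation-contraction coupling, and 3 of 14 for developmental muscle genes. Mef2c and Mef2d, partners of the myogenic factors, Eya4 and Nfix were regulators with a promoter peak in both libraries, as was Myf6, with heights of 0.406 and 0.879. Myod1, the myogenic determination factor, had a promoter peak in replicate 1 only (height 1.59), as did Ryr1, the calcium release channel of the sarcoplasmic reticulum (1.46), and Myh8, the perinatal myosin heavy chain (5.53). Acta1, skeletal alpha-actin, and Pax7, the transcription factor of satellite cells, had one in replicate 2 only (heights 1.22 and 1.19). Neither library had a promoter peak at Des, Tnnt3, Myog, Myf5, Chrng, Chrne, Myh1, Myh2, Myh3, Myh4 or Myh7; Tnnt3 and Chrng, the fetal subunit of the acetylcholine receptor, each had 3 shared distal peaks.

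Among the cell types that lie between muscle fibres, 5 of 15 Schwann cell genes, 4 of 15 tenocyte genes and 3 of 15 fibro-adipogenic, lymphocyte and adipocyte genes had a shared promoter peak, none of these lists differing from other genes by the test. Scx, a tendon transcription factor, had promoter peaks of 1.03 and 0.943, and Pdgfra, the receptor that marks fibro-adipogenic cells, of 2.57 and 1.88. Adipoq had a promoter peak in replicate 1 only (0.513), and Pecam1, Rgs5, Sox10 and Ptprc had none in either library. Lists below other genes were endothelial, macrophage and cardiac (0 of 15 each, log2 odds ratio -4.67, adjusted p = 0.00240, Fisher's exact test), hepatocyte and keratinocyte (1 of 15 each), erythroid and pancreas (1 of 14 each), mural and germline (2 of 15 each), and the hindlimb and forelimb position lists (1 of 13 each, log2 odds ratio -3.30, adjusted p = 0.0238). Shared peaks must overlap, so these counts leave out promoters with separate peaks in the 2 libraries. A promoter peak in each library, overlapping or not, was found at 2 of 15 endothelial (Kdr and Sox17), 5 of 15 mural and 0 of 15 macrophage and cardiac genes. Without the library labelled replicate 1 the hindlimb list reversed to 9 of 13 (log2 odds ratio 1.09, not called) and the forelimb call ended (adjusted p = 0.223, Fisher's exact test). The endothelial call ended in the other list, with reciprocal overlap and without replicate 2 (7 of 15, Fisher's exact test, adjusted p = 0.164), and the mural call in the other list, with 1 bp or reciprocal overlap and in each library alone (8 of 15 and 5 of 15, 0.341 and 0.252). Alb, Krt14, Nkx2-5, Pitx1, Tbx4, Tbx5 and Hoxc4 had no promoter peak in either library, while neuronal genes (3 of 15) and immediate-early genes (10 of 14) were not called and Hoxc10, a posterior limb Hox gene, had a peak in both (1.31 and 2.11). Promoter CpG content sets much of this: the share of genes with a shared promoter peak was 3.52%, 53.8% and 77.9% in the 3 CpG classes from low to high. With the lists compared within CpG classes by the Mantel-Haenszel test the housekeeping (log2 odds ratio 1.35), circadian (2.14), sarcomere (-0.75), macrophage (-1.05), erythroid (-1.88), mural (-1.17), hepatocyte and pancreas (-3.01) calls ended. That left 0 lists above and 7 below other genes: endothelial, cardiac, germline, keratinocyte, hindlimb and forelimb as before, and neuron (-2.77), which was not called over all genes. The libraries differed within CpG classes. Neuron was called above other genes in replicate 1 (log2 odds ratio 1.76) and below them in replicate 2 (-2.15). Muscle metabolism was called above other genes in replicate 2 (log2 odds ratio 1.68) and lay at 2.11 in replicate 1, not called. Hindlimb was called below in replicate 1 (-6.31) and was not called in replicate 2 (-0.18). The sarcomere call also ended in the stricter selection, in the other list, with reciprocal overlap, with a 2 kb promoter and in replicate 1 alone (adjusted p = 0.134, Fisher's exact test).

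Away from promoters, the immediate-early genes, which respond within minutes to stimulation, stood out in the shared peaks. They had a mean of 2.36 ± 0.929 (SD over 14 genes) shared distal peaks, between 1 and 50 kb from a TSS, where random lists matched on promoter status had a mean of 0.614 (adjusted p = 0.0174 over 29 lists, permutation of gene lists). Fos had 4 and Fosb, Dusp1 and Ier2 had 3 each. Of the other 28 lists none was called, with the sarcomere list at a mean of 1.03 against 0.524 in random lists and the neuron list at 1.07 against 0.516. In replicate 1 alone the immediate-early list was not called (adjusted p = 0.122, permutation of gene lists). The genes with the most shared distal peaks, of those whose windows do not overlap, were B4galt5, a galactosyltransferase (21), Tmem107 (16), Fcgr3 (14), and Nfic, Sfi1 and Tns1 (13 each), followed by Creb3l1 and Tnrc18 (10 each) and Rhof and Trim27 (9 each).

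The third comparison set the 2 libraries against each other over the same gene lists, with replicate 1 limited to its 26804 tallest peaks. The library labelled replicate 2 carried more distal peaks at sarcomere, fast fibre and limb position genes, the last mostly at the Hoxa cluster, and the library labelled replicate 1 more at neuronal genes. Sarcomere genes had a mean of 3.20 ± 5.30 distal peaks (SD over 30 genes) in replicate 2, 1.70 more than in replicate 1 (adjusted p of the difference 0.00387, permutation of gene lists), and fast fibre genes 3.20, which is 1.87 more (adjusted p = 0.0261). Posterior hindlimb genes, which include Hoxa9 to Hoxa13, had 6.62 ± 5.91 and 1.38 ± 0.506 (SD over 13 genes, adjusted p = 0.00290 by permutation). Forelimb and anterior Hox genes had 2.69 and 0.769 (adjusted p = 0.0499 by permutation). Neuronal genes went the other way, with 1.47 ± 1.41 in replicate 2 and 4.40 ± 5.99 in replicate 1 (SD over 15 genes, adjusted p = 0.00290 by permutation).

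Within these lists a few loci held many of the peaks. In the library labelled replicate 2 the sarcomere genes summed to 96 distal peaks, from 90 distinct ones, and the 86 of the hindlimb genes came from 24 distinct ones. Of the sarcomere sum, 21 were counted at Tnnc1 (slow troponin C), 19 at Mybpc2 (fast myosin-binding protein C) and 10 at Myoz3. These genes are named after their values were seen, and 10 of the 30 genes had none. A distal peak counts for every gene with a TSS within 50 kb. Peaks counted at these genes may therefore also count for neighbours outside the list. Some listed peaks overlap others of their own list (1.78% in replicate 1, 9.48% in replicate 2), so an open stretch can count more than once. Counts per cluster and gene here are from whole lists, with those in the tallest 26804 peaks of replicate 1 added as equal-number counts. Across the Hoxa cluster (chromosome 6, 52155590 to 52260880) replicate 2 had 44 peaks and replicate 1 had 6 (equal-number count 2); between Hoxa9 and Hoxa13 the counts were 35 and 1 (1), between Hoxc9 and Hoxc13 8 and 1 (0), and between Hoxd9 and Hoxd13 5 and 1 (0). With overlapping peaks merged, replicate 2 had 34 in the Hoxa cluster, 26 between Hoxa9 and Hoxa13, 7 between Hoxc9 and Hoxc13 and 5 between Hoxd9 and Hoxd13, and the counts of replicate 1 stayed. The Hoxb cluster had 6 peaks in replicate 1 (equal-number count 1) and 0 in replicate 2. The cluster of fast and developmental myosin heavy chains from Myh3 to Myh13 (chromosome 11, 67078300 to 67371586) had 22 peaks in replicate 1, an equal-number count of 3, and 1 in replicate 2. Rbfox3, the RNA-binding protein known as NeuN that marks neurons, had 63 distal peaks in replicate 1 (equal-number count 23) and 5 in replicate 2, and Neurod2, a neuronal transcription factor named here after its values were seen, 31 (12) and 2.

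**Figure D2:**
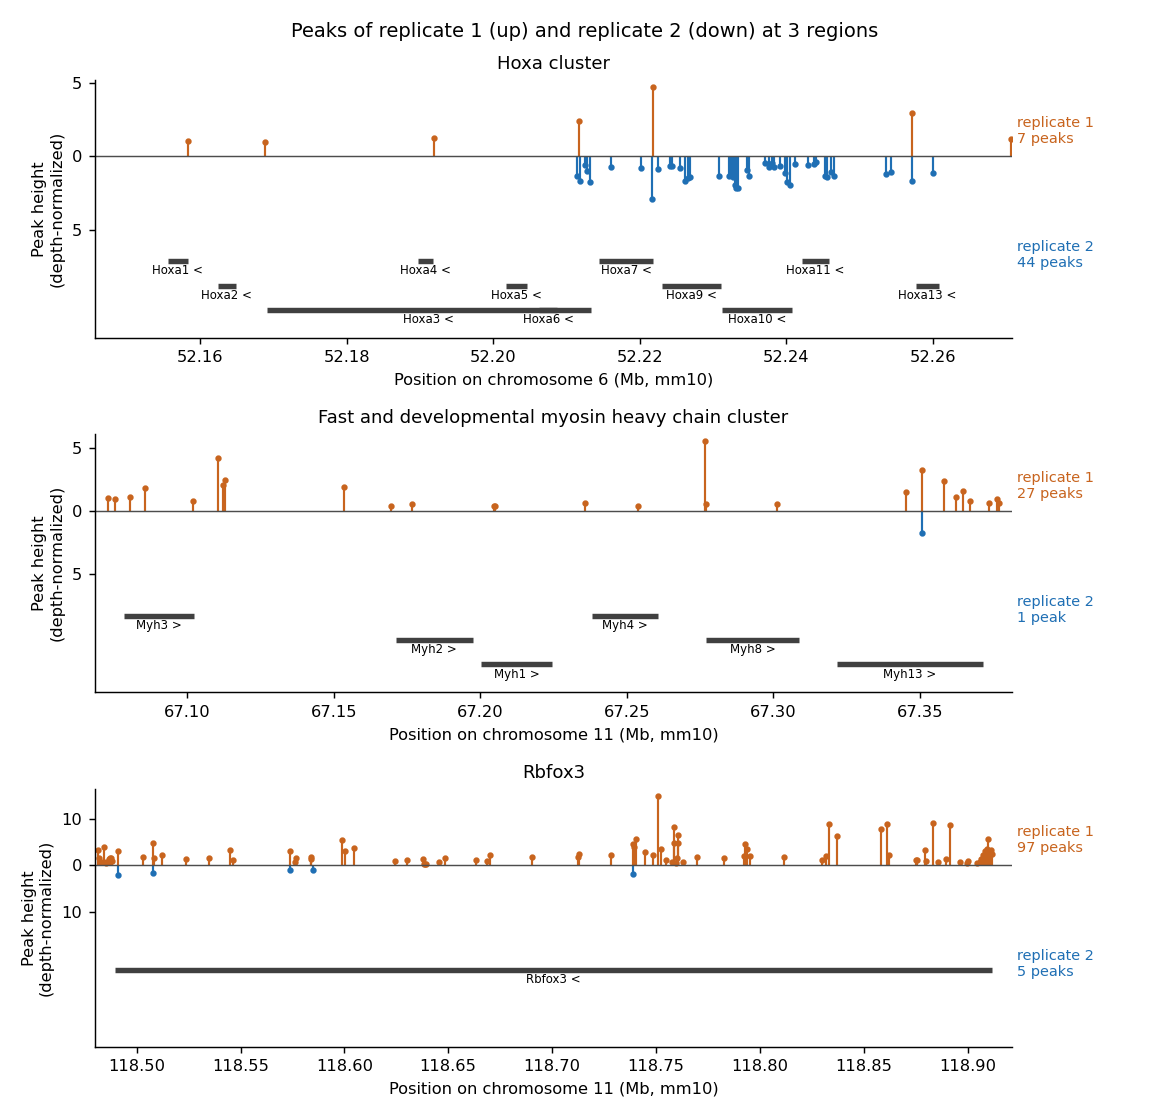
Peaks of the library labelled replicate 1 (upward) and replicate 2 (downward) along the Hoxa cluster, the fast and developmental myosin cluster and Rbfox3, each with 10 kb on either side; line length is depth-normalized peak height (y axis), the x axis is mm10 position in Mb, and grey bars are the Hoxa, Myh and Rbfox3 genes with arrowheads for strand. The 3 regions hold 7 and 44, 27 and 1, and 97 and 5 peaks in the whole lists of replicates 1 and 2.

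Each library alone showed other lists above random. In replicate 2 these were sarcomere, fast fibre, slow fibre (mean 2.47), immediate-early (3.14), hindlimb and forelimb genes. In the tallest peaks of replicate 1 they were neuron, myogenic regulators (3.00 against 0.989 in random lists, adjusted p = 0.00580 by permutation), excitation-contraction coupling (2.33), macrophage (2.13), circadian (3.20) and immediate-early genes (3.29). Nfix, a factor of the fetal muscle programme, with 23 peaks, and Mef2d, with 13, led the regulators. At promoters the exact McNemar test called 0 of 29 lists and had 2 at an unadjusted p under 0.05: 9 hindlimb genes had a promoter peak in replicate 2 only and 0 in replicate 1 only (exact p = 0.00391, adjusted 0.113), and 8 neuronal genes in replicate 1 only and 1 in replicate 2 only (exact p = 0.0391, adjusted 0.518). In its whole list the library labelled replicate 1 had a promoter peak at all 15 neuronal genes (66.7% of other genes, log2 odds ratio 3.95, adjusted p = 0.0108, Fisher's exact test), but in its tallest 26804 at 11, which was not called (adjusted p = 0.103, Fisher's exact test); replicate 2 had one at 4, namely Rbfox3, Camk2a, Snap25 and Syn1. Single genes matter for many of these calls. With the member that had the most distal peaks left out of 1 list at a time, neuron in replicate 1 without Rbfox3 (mean 3.07 against 1.16, permutation, adjusted p = 0.0203) kept its call. So did sarcomere without Tnnc1 (0.0145) and immediate-early without Btg2 (0.0454) in replicate 2. With the top member left out of every list at once, sarcomere kept its call (permutation, adjusted p = 0.0145). Neuron in replicate 1 (0.0812) and immediate-early genes in replicate 2 (0.0909) then did not. With 1 list changed at a time, calls ended in replicate 1 for myogenic regulators without Nfix (1.95 against 0.973), excitation-contraction coupling without Stac3 (1.86 against 0.928) and circadian genes without Nr1d1 (2.57 against 1.36). They also ended, with means that moved little, for macrophage genes without Laptm5 (1.79 against 0.682, permutation, adjusted p = 0.0764) and immediate-early genes without Btg2 (2.92 against 1.25, 0.0657). In replicate 2 they ended for fast fibre genes without Mybpc2 (2.07 against 0.680), slow fibre genes without Tnnc1 (1.14 against 0.728) and forelimb genes without Hoxa3 (1.67 against 0.723). Of the differences between libraries, sarcomere without Tnnc1 (1.17 more in replicate 2, permutation, adjusted p = 0.0261) stayed. Those of neuron without Rbfox3 (a difference of -1.86, permutation, adjusted p = 0.143), fast fibre without Mybpc2 (0.157) and forelimb without Hoxa3 (0.299) ended. With overlapping peaks merged, sarcomere, fast fibre, neuron and hindlimb differences stayed and the forelimb difference ended (permutation, adjusted p = 0.0615), as did the calls of slow fibre, immediate-early and forelimb genes in replicate 2. Neighbouring Hox genes share peaks, so the hindlimb calls rest on few loci. With 1 gene per cluster, 5 genes in all, the hindlimb mean in replicate 2 was 4.80 against 0.775 (permutation, adjusted p = 0.0503) and the difference between libraries 3.40 (0.113), neither called. Without the Hoxa genes the mean was 2.89 against 0.843 (permutation, adjusted p = 0.123) and the difference 1.33 (0.307). The forelimb calls ended in the same tests.

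**Figure D3:**
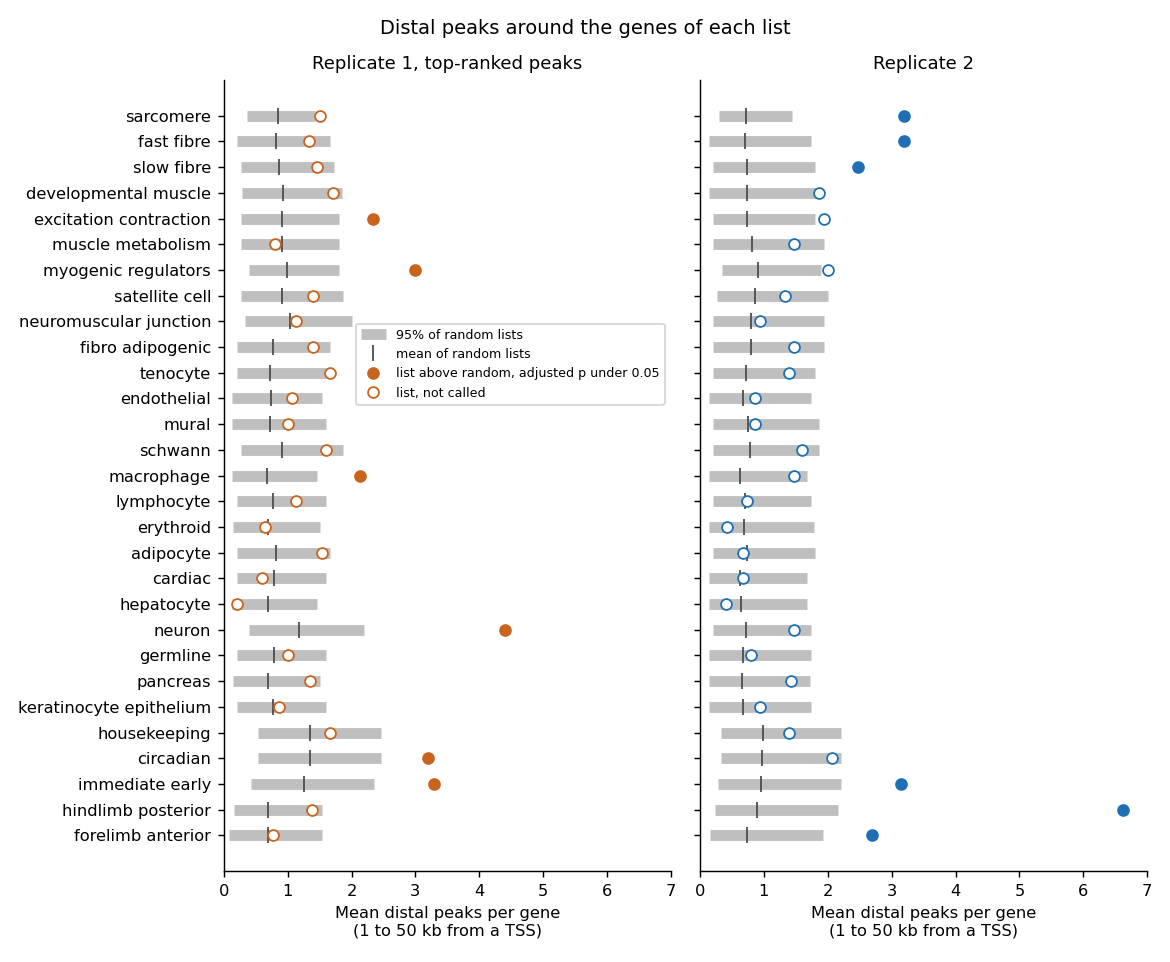
Mean number of distal peaks per gene (x axis) for the 29 gene lists (y axis) in the tallest 26804 peaks of replicate 1 (left) and in replicate 2 (right). Grey bars span 95% of 10000 random lists, ticks mark their mean, and filled points are lists above random with an adjusted p under 0.05: neuron stands at 4.40 on the left and hindlimb genes at 6.62 on the right.

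The fourth question was which transcription factor motifs the shared distal sites carry. The binding motif of CTCF, the insulator protein, was present in 20.6% of the 6754 shared distal peaks and in 0.170% of flanking windows (log2 odds ratio 7.24, 95% interval 6.65 to 7.84). The E-box CAGCTG, which the MyoD family of myogenic factors binds, was present in 15.9% against 7.74% (log2 odds ratio 1.18, interval 1.05 to 1.31). In all, 9 of 22 motifs were above flanks: besides these, NFI (5.09), CRE of the CREB family (3.10), NRF1 (2.77), ETS (1.70), the GC box of SP and KLF factors (1.48), NFY (0.75) and the E-box CACGTG (0.51), each as log2 odds ratio. Another 4 were below flanks, namely GATA-TAL of erythroid cells (-2.32), ERR (-1.48), RUNX (-0.64) and SOX (-0.38). MEF2 (-0.18), TEAD (0.04), AP-1 (0.16), MEF3 (-0.06), CArG of SRF (-0.31), GRE (0.19), PU.1 (-0.72), DR1 (-3.25) and HNF1, with 0 matches in peaks, were not called by Fisher's exact test. Peaks had a GC content of 56.8% and flanks 47.3%. Against the peaks' own sequences with dinucleotides shuffled the CAGCTG log2 odds ratio was 0.29, and MEF2 (2.91) and RUNX (0.76) were above background while NFY (-0.15), ETS (1.12), NFI (3.00), ERR, GATA-TAL and SOX were not called. ETS was not called in either library alone either (0.74 without replicate 1, 0.45 without replicate 2), nor were RUNX (-0.31) and ERR (-0.75) without replicate 1 and GATA-TAL (-0.35) without replicate 2.

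Motifs were also compared in distal peaks not shared at equal numbers of tallest peaks (10028 in replicate 1, 5773 in replicate 2). Many of the 5773 overlapped a lower peak of replicate 1, since 2801 distal peaks of replicate 2 were unshared over the whole lists. They are thus not all sites of replicate 2 alone. CAGCTG was more common in the library labelled replicate 1 (log2 odds ratio -0.58 for replicate 2 over replicate 1, adjusted p = 6.03e-19, Fisher's exact test). CTCF (4.94% against 7.86%, log2 odds ratio 0.72), RUNX (0.74) and SOX (0.39) were more common in replicate 2, and NFY (-0.48), the GC box (-0.82), GRE (-1.24) and GATA-TAL (-3.85) in replicate 1.

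**Figure D4:**
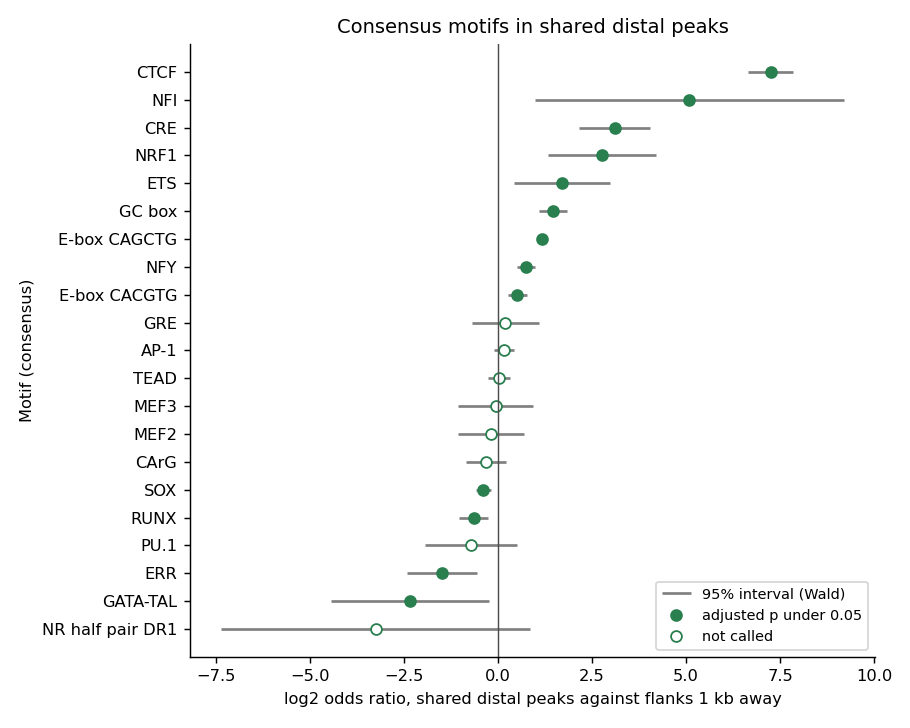
Log2 odds ratio (x axis) of each consensus motif (y axis) in the central 150 bp of shared distal peaks against windows 1 kb away on either side, with 95% Wald intervals; filled points have an adjusted p under 0.05. CTCF lies at 7.24 and CAGCTG at 1.18, and HNF1, without a match in peaks or flanks, is not drawn.

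Footprints, short protected stretches within open sites that the authors called, gave a similar order of motifs. Unless a library is named, the ratios below add the counts of both. A match in peaks of both libraries thus enters from each, and intervals on the added counts may be too narrow. Replicate 1 gave 7.62 of the 9.13 Mb of padded footprints. CTCF matches were 58.1 times as dense inside footprints as in the rest of the peaks that hold them (exact 95% interval 50.6 to 66.9), NFI 36.1, NRF1 23.6, CRE 8.32, GC box 4.51, DR1 3.95, ETS 1.61, NFY 1.45, CAGCTG 1.34 (1.31 to 1.37) and CACGTG 1.08 times. Several ratios differed between the libraries, by intervals that do not overlap. In replicates 1 and 2 NRF1 was 67.1 and 16.8 times as dense, CRE 13.9 and 5.81 and GC box 6.49 and 3.28, with CTCF at 61.9 and 58.0. NFI was at 39.8 and 8.90 with overlapping intervals (21.3 to 84.0 and 2.22 to 51.1). Its ratio in replicate 2 rests on 9 matches inside footprints and 3 outside. These differences were not tested. Densities were lower inside footprints for GATA-TAL (0.460), MEF3 (0.565), ERR (0.583), AP-1 (0.675), GRE (0.675), RUNX (0.713) and SOX (0.825). MEF2 (0.810), CArG (0.987) and PU.1 (0.785) were not called, nor were TEAD and HNF1. Replicate 1 had 468215 footprints and replicate 2 had 115528, of which 66.6% and 63.5% lay in peaks, with 2.72 ± 1.76 and 2.74 ± 2.59 per peak (SD over peaks), and 4.08 ± 1.63 in the 26804 tallest peaks of replicate 1. At least 1 footprint lay in 90.7% of peaks in replicate 1 and 79.2% in replicate 2. Of all footprints 9.64% and 43.2% overlapped a footprint of the other library. Within shared peaks 39.3% of the footprints of replicate 1 and 64.0% of those of replicate 2 overlapped a footprint of the other library. Footprints are dense in peaks (14.3 and 10.4 per kb over all peaks of replicates 1 and 2). Part of this overlap may thus arise by chance, and the part was not measured. Without replicate 1 the CACGTG, DR1 (1.48 times), MEF3 (0.539), GRE (0.674) and GATA-TAL (0 matches inside, 12 outside) calls ended, those of MEF3 and GRE at much the same ratio, and TEAD was below (log2 rate ratio -0.44, exact test, adjusted p = 0.00474). MEF2 was called lower in replicate 1 alone (0.697 times, exact test, adjusted p = 0.00513) and without padding (0.640), and lay at 1.48 in replicate 2, not called. PU.1 was likewise called lower in replicate 1 alone (0.706 times, exact test, adjusted p = 0.0371) and without padding (0.603), and lay at 1.17 in replicate 2, not called.

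The last comparison was of chromosomes. Peaks were 0.367 and 0.348 times as dense on the X chromosome as on autosomes in replicates 1 and 2. Chromosome 11 was 1.52 and 1.69 times as dense as the autosomal mean. On the Y chromosome there were 31 and 8 peaks, of which 22 and 1 lay beyond 90 Mb. No promoter peak was found in either library at Ddx3y, Kdm5d, Eif2s3y or Uty, the broadly expressed genes of the Y chromosome, in these samples labelled female. Xist, the RNA of the inactive X chromosome, had 2 promoter peaks in replicate 1 (highest 1.37) and 0 in replicate 2.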

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

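The distal comparison between libraries, the removal of single genes or of the Hoxa cluster and the 7 added neural lists were chosen only after the neuron result was seen; the predictions for the tests below were written before their values.

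Neuronal genes had more distal peaks in the library labelled replicate 1 (mean 4.40) than in replicate 2 (1.47), while posterior Hox and sarcomere genes had more in replicate 2. Greater depth alone would raise all genes alike. It is argued against by the neuron list staying above random lists at the same number of tallest peaks (permutation, adjusted p = 0.0058). Without Rbfox3 the adjusted p was 0.0203 by permutation, or 0.0812 with every list trimmed of its top member. The difference between libraries was not called without Rbfox3 (permutation, adjusted p = 0.143). A library of mostly neural tissue stays open. At distal sites 0 of the 7 added neural lists stood above random (permutation, adjusted p 0.620 to 0.672), the result written beforehand as counting against it. A missed threshold is weak evidence, since the test missed 6 of 20 planted lists and all 7 lists lay above their random mean. Promoters cannot decide it. In the whole list of replicate 1, 15 of 15 neuronal (Fisher's exact test, adjusted p = 0.0108) and 15 of 15 synapse genes (0.0143) had a peak. So did 15 of 15 housekeeping and circadian and 14 of 14 immediate-early genes, and 98.3% of all genes in the highest CpG class. Within CpG classes the neuron list was above other genes there (log2 odds ratio 1.76), but so was the adipocyte list (2.75). At equal numbers neither the neuron nor the synapse list was called. Gastrocnemius with nerve mixed in would keep the muscle sites of replicate 2. Yet distal peaks of replicate 2 near the 9 muscle lists had an FDR base in replicate 1 less often than all its other distal peaks (55.3% against 84.7%). At like height the odds ratio was 0.32 (95% interval 0.220 to 0.464). In the other direction, distal peaks of replicate 1 near these lists had such a base in replicate 2 more often than others (odds ratio 1.33, interval 1.14 to 1.55). Many of the peaks of replicate 2 near these lists lie at a few loci. Myod1, Ryr1 and the Myh3 to Myh13 cluster did have peaks in the library labelled replicate 1, so muscle in it is not excluded. A mislabelled library from another tissue and a difference between pools of animals stay open, as neither was tested, and no biological explanation was tested because the design has a single group.

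Promoters took 64.6% of the peaks of replicate 2 and 26.0% of those of replicate 1. A shorter list being richer in promoters in any library explains part of this at most, since the 26804 tallest peaks of the library labelled replicate 1 had a promoter share of 48.6%, more than 5 percentage points below replicate 2. Differences in enrichment between the libraries were not tested, and no biological explanation was tested.

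On the Y chromosome below 90 Mb, in intervals that no comparison above used, 5971 bases in replicate 1 and 2654 bases in replicate 2 had an FDR under 0.05, in samples labelled female. What marked them was a count above 0, which any base would pass, and no background such as mismapped or X-homologous sequence was measured.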

How the results depend on the processing

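Settings chosen only after seeing the data were the difference of distal peaks, the tallest peaks and the other list for peak and footprint counts, window-length matching, 1 gene per Hox cluster, the merging of overlapping peaks and the removal of single genes or of the Hoxa cluster. No paired analysis was possible because the design has 1 group of 2 libraries. Ranking footprints by score was not run, as the score is constant. The cause of the changes below was not tested. The share of peaks shared in replicates 1 and 2 was 19.1% and 79.2% in the stricter selection, 17.0% and 67.6% in the other list, 45.8% and 45.8% at equal numbers of tallest peaks, 18.9% and 79.5% with 1 bp of overlap, 16.5% and 71.1% with overlapping peaks merged, and 9.72% and 41.7% with reciprocal overlap, where the rank correlation was 0.601. The promoter share of shared peaks was 71.9% in the stricter selection, 53.0% in the other list, 69.5% at equal numbers, 66.5% with 1 bp, 54.8% with reciprocal overlap, 59.7% within 500 bp, 68.0% within 2 kb, and 26.0 to 64.6% with either library left out; it was 48.6% in the tallest peaks of replicate 1.

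Lists above other genes by promoter peaks (2 in the report) were 4 in the other list, 0 within CpG classes and 3 to 4 with a library left out. Lists below (12) were 7 in the other list, 0 with reciprocal overlap, 7 within CpG classes and 10 to 11 with a library left out. With a library left out the log2 odds ratio of the hindlimb list ranged from -4.59 without replicate 2 to 1.09 without replicate 1 (adjusted p = 0.325, Fisher's exact test), and of the neuron list from -1.54 without replicate 1 to 3.95 without replicate 2. Lists above random by distal peaks (1) were 2 in the other list, 3 at equal numbers, 3 with 1 bp, 0 with reciprocal overlap, 0 within 25 kb, 2 within 100 kb, 2 unmatched, 1 matched on window length, and 1 without replicate 2 to 6 without replicate 1. With random lists matched on window length the 5 differences between libraries stayed under 0.05 (permutation, adjusted p 0.00290 to 0.0313), while excitation-contraction coupling in replicate 1 (1.37 above random, 1.42 before, adjusted p = 0.0512) and slow fibre (1.64, 1.74 before, 0.0561), immediate-early (2.19, 2.18 before, 0.0551) and forelimb genes (1.89, 1.95 before, 0.0561) in replicate 2 did not, at much the same differences, by permutation. Random lists on distal peaks gave 5 lists that differ between libraries, and 4 with overlapping peaks merged, against 0 by exact McNemar tests on promoter peaks. Place and test changed together here, so the change cannot be put down to either alone.

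Motifs below flanks (4) were 2 with reciprocal overlap, 0 with shuffled sequences, and 2 to 5 with a library left out. With shuffled sequences MEF2 turned to 2.91, RUNX to 0.76 and NFY to -0.15, the last not called. In footprints TEAD turned to -0.26 without padding and ranged from -0.44 without replicate 1 to 0.0202 without replicate 2, and CACGTG from -0.0367 without replicate 1 to 0.18 without replicate 2. The other list held 189128 and 46786 peaks, with an X density of 0.418 and 0.413 and 2.09 and 2.12 footprints per peak; the tallest peaks of replicate 1 held 4.08. Of the tests of single lists and motifs under alternatives, 262 of promoter lists, 361 of distal lists, 190 of motifs in peaks and 55 of motifs in footprints kept direction and side of the threshold. Another 38, 3, 19 and 4 lost their call, and 17, 13, 8 and 4 gained one. Direction reversed in 2 tests of promoter lists, 3 of motifs in peaks and 3 of motifs in footprints. Some unshared peaks may lie below the threshold of the other library: 91.8% of the unshared promoter and 45.6% of the unshared distal peaks of replicate 2, and 47.4% and 12.2% of those of replicate 1, had an FDR base there. Of all peaks of replicate 2, 97.6% of promoter and 83.9% of distal ones had such a base in replicate 1.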

Other observations

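The genes, listed or not, around which most distal peaks gathered differed in part between the 2 libraries. They are named here after their values were seen, as the highest of a library. In replicate 2 these were B4galt5 (46), Sik1, a kinase induced by cAMP signalling (44), Smok2a (27) and, at 22 each, Bap1, a deubiquitinase of histone H2A, Nfic and Rapgef1. In the whole list of the library labelled replicate 1 they had, in this order, 46, 6, 2, 6, 45 and 15, and in its 26804 tallest peaks 4, 0, 0, 2, 10 and 5. In all peaks of replicate 1 they were Gse1 (70), Lgals3bp (69), Rbfox3 (63), Kalrn, a guanine nucleotide exchange factor of synapses (58), and Nav2 (54), with 10, 3, 5, 2 and 1 in replicate 2. The lists differ in length, and these counts stood at percentiles 99.3, 91.5, 97.4, 82.2 and 59.9 of genes in replicate 2. In the 26804 tallest peaks of replicate 1 the same genes had 23, 6, 23, 6 and 8.

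The tallest shared peak by summed ranks lay between protein-coding genes on chromosome 17 (39846781 to 39846900, nearest gene Esp38), with heights of 39.5 and 89.6. Of the other 9, 7 lay at promoters, those of Dynlt1b (55.1 and 8.17), Hjurp, Fbh1, Acin1, Fxr2, Nr2c2 and Nup107, and 2 lay between protein-coding genes near Gm15319 and Gm31371 on chromosome 8. No filter for repeats or regions of excess signal was applied here, so the tallest peaks may include such regions.

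Among distal peaks of replicate 2, 100% of the 21 near housekeeping genes had a base with an FDR under 0.05 in replicate 1, against 46.7% of 90 near sarcomere genes and 29.2% of 24 near posterior hindlimb genes. In the other direction 28.2% of 932 distal peaks of replicate 1 near the 9 muscle lists had such a base in replicate 2, against 19.1% of others (odds ratio 1.33, 95% interval 1.14 to 1.55 at like height), and 16.7% of 204 near neuronal genes did (odds ratio 0.528, interval 0.358 to 0.778).

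Of the 7 added neural lists, synapse genes had more promoter peaks than other genes in the whole list of replicate 1 (15 of 15 against 66.7%, Fisher's exact test, adjusted p = 0.0143) and photoreceptor genes fewer (4 of 15). Forebrain (13 of 14), cerebellar (12 of 15), astrocyte and oligodendrocyte (11 of 15 each) and peripheral and motor neuron genes (8 of 15) were not called. In its 26804 tallest peaks 0 lists were above and 3 below other genes. Compared with replicate 2 there, 8 cerebellar genes had a promoter peak in replicate 1 only and 0 in replicate 2 only (exact p = 0.00781, adjusted 0.0547), with 6 and 0 for synapse and 4 and 0 for forebrain genes. By distal peaks in the whole list of replicate 1 the cerebellar list had a mean of 9.87 against 5.40 in random lists (permutation, adjusted p = 0.0588).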
